A study of Homo sapiens with 18 samples.

How the data were processed

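RNA of the Burkitt lymphoma lines Raji and DG75, untreated or exposed for 1 h to 50 µM Bay-11 or 75 µM TPCK, was hybridised to 18 Illumina bead arrays, 3 in each of 6 groups. Per the labels' protocols, RNA was isolated with Trizol, cleaned on RNeasy columns with DNase treatment and labelled with an Ambion MessageAmp kit. The raw table deposited by the authors holds log2 values of the raw bead signal, per the file headers, for 49576 probes, with no background subtraction or normalization between arrays. Beside each signal the deposited table gives a detection p-value per probe, per the file headers. The processing software, its version and a genome build are not given in the sources used here. Column names of this table give the cell line and the treatment, and arrays are named here by the number with which each column name begins, which appears in no label. All 18 columns were tied to a group, and 0 columns of per-sample values were left unused.

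A second deposited table, of log2 values, lists 22789 probes and carries replicate numbers. Its 9 Raji columns and the first DG75 Bay-11 column are centred near 0 and hold blanks. Medians were -0.04, -0.11 and -0.09 for Raji control replicates 1 to 3, 0.06, 0.15 and -0.03 for Raji TPCK, 0.09, 0.15 and -0.05 for Raji Bay-11 and 0.12 for DG75 Bay-11 replicate 1. The other 8 DG75 columns equal columns of the raw table, with medians of 6.41 and 6.09 for Bay-11 replicates 2 and 3, 6.25, 6.13 and 5.93 for the controls and 6.70, 6.07 and 6.43 for TPCK. The scale is log2, and the arrays used for centring and the normalization of the centred columns are unknown. This table served only as an alternative, for comparisons whose columns share a scale. It holds processed values for the Raji comparisons and raw signals for DG75 TPCK against control. Deviations of same-numbered Raji TPCK and Bay-11 columns from their group means correlated with 0.140, 0.128 and 0.238, each over 0.1, so for that comparison the replicate numbers were taken to pair the samples. The pairing comes from these values alone, not from the labels, and columns with different numbers were not correlated for comparison.

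For the main values, raw signals were corrected with normexp, using the detection p-values to estimate background, with an offset of 16, and were quantile normalized with neqc of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was under 0.01 on at least 3 arrays, which left 17652 probes. Gene symbols came from a probe table of the platform annotation holding 17112 probes, of which 17109 had 1 symbol and 3 had several, while 32467 probes of the raw table were unnamed here. Through Entrez identifiers 17095 probes matched the reference gene table, and 0 symbols needed updating. Among kept probes 14195 had 1 symbol and 3457 had none. The kept probe with the highest mean over all arrays stood for each gene, which gave 10697 genes. The reference gene table, of assembly GRCh38.p14, served for names and for which genes contain which small RNAs, without regard to strand, and no coordinates are given.

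A linear model with 6 group means was fitted to all 18 arrays with lmFit and moderated with eBayes of limma, with 12 residual and 4.26 prior degrees of freedom. Each gene's p was adjusted within a comparison by the Benjamini-Hochberg method, and a gene with an adjusted p under 0.05 is called. Comparisons were each treatment with its control, TPCK with Bay-11 in each line, the untreated lines with each other, and the difference between lines in each treatment effect. The 26 gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists with at least 5 measured members, 23 in all, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Genes undetected on all arrays of a group have only a bound there. Such a fold is given as "at least", from the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value of a detected probe.

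Named genes are, per comparison, the 6 with the highest and the 6 with the lowest change among called genes whose groups do not overlap and whose symbol is not a placeholder. To these come up to 4 called members with the largest change of each list that was called or stands among the first 9 lists. A further 20 genes of the NF-kB, stress, early response and BCL2 families were fixed. Of these, only BCL2A1 in DG75 after TPCK was called in a treatment comparison, and treatment values of most others are not printed. TRIAP1, DUSP1, the shared genes, further members of lists where 5 or fewer were called on 1 side, genes that differed between lines only without arrays 7 and 10, CXCL8 where it was not called and genes of the arrays that stood apart were named after their values had been seen. Correlations of effects over genes were compared with 50 simulations of unchanged groups sharing 3 controls, drawn from each gene's spread.

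The arrays were compared before averaging. Of 153 pairs, 0 held identical values, and the lowest correlation of an array with its own group ran from 0.952 to 0.991. The test was checked on simulated data built on the 10697 genes, with 200 genes changed in each of 5 draws. In the Raji Bay-11 comparison 31.9% of genes changed 1.5-fold were recovered, 81.8% of those changed 2-fold and 99.7% of those changed 4-fold, and 5.79% of calls were of unchanged genes. For the difference of Bay-11 effects between lines, 6.57%, 44.8% and 97.6% were recovered. A list of 30 genes shifted by 0.3 was found in 5 of 5 draws. Simulated values varied independently between genes, so these rates do not cover correlated genes or arrays that stand apart.

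Alternatives were no background correction, no normalization between arrays, centring on the median, other detection filters, all probes, a fit to the compared groups only, array weights, an estimated correlation in camera, the second deposited table with and without the replicate number as a block, and each array left out in turn. Leaving out the arrays numbered 7 and 10 together was added after the data had been examined. No group had 4 to 10 arrays, so no test for outlying arrays was applied. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.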

Results

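Gene expression was measured in Raji and DG75, 2 cell lines grown from Burkitt lymphoma, a B cell tumour. Raji carries the Epstein-Barr virus and DG75 does not. Each line was left untreated or was exposed for 1 h to 50 µM Bay-11 or 75 µM TPCK, both used to block activation of the transcription factor NF-kB, whose network is the subject of the design text. Bay-11 is used against phosphorylation of the NF-kB inhibitor IkB, and TPCK is a chloromethyl ketone that blocks chymotrypsin-like proteases. The design text names TPCK for Raji only, while sample titles and column names also give it for DG75, and these were followed. Each of the 6 groups held 3 bead arrays, 18 in all. Between 13072 and 15903 probes were detected per array, and the mean raw signal per probe ran from 171 to 298. In Raji it was 171 to 202 on control arrays, 206 to 256 on Bay-11 arrays and 243 to 282 on TPCK arrays. In DG75 it was 182 to 235, 209.9 to 273 and 208 to 298. The number of arrays limits the precision of all values. The labels do not state whether arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Control arrays of both lines are numbered 13 to 18 and treated arrays 1 to 12. What these numbers mean is not stated. A batch or order behind them could not be told apart from treatment, also for changes found in both lines. Changes are log2 fold changes ± SE with n = 3 arrays per group, and p-values are limma's, adjusted by the Benjamini-Hochberg method. A total of 10697 genes was tested, and 256 changed in at least 1 of the 4 comparisons of a treatment with its control.

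2 arrays stood apart from their groups. On the DG75 TPCK array numbered 7 in the deposited table, 687 probes were detected that were detected on no other array, against 50 to 327 on the other arrays. Of these, 50 exceeded log2 8, against 0 on any other array. They included transcripts of other tissues, such as SCGB2A2 at 13.87 and COL1A2 at 10.03. On the DG75 Bay-11 array numbered 10, 205 probes that were bright on the DG75 control arrays were over 2 log2 units below their mean there. Counts without both arrays are given beside each comparison and were chosen after the data had been examined.

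In Raji, 161 genes changed after 1 h of Bay-11, 94 up and 67 down, and 30 of them by over 2-fold. FOSB, a subunit of the transcription factor AP-1, fell most (log2 fold change -1.74 ± 0.16, adjusted p = 3.38e-05). The activation marker CD69 (-1.39 ± 0.18, adjusted p = 0.00299) and the chemokine CXCL8 (-1.09 ± 0.19, adjusted p = 0.0120), both NF-kB targets, also fell. SNORD46, a small nucleolar RNA, rose 4.15-fold (2.05 ± 0.16, adjusted p = 5.28e-06). Here and below, whether probes of such genes report the mature RNA or a longer transcript was not tested.

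Among 22 measured p53 targets, 5 fell in Raji after Bay-11 and 0 rose (9 fell and 1 rose when adjusted over the list alone). They were GADD45A (-1.01 ± 0.15), the cell cycle inhibitor CDKN1A (-0.89 ± 0.13), the death receptor FAS (-0.76 ± 0.14), the nuclease AEN (-0.73 ± 0.11) and TRIAP1. The list's median was -0.45 (adjusted p = 3.44e-06; adjusted p = 0.00635 with an estimated correlation). Of 33 immediate early genes, 5 fell and 0 rose (9 fell and 2 rose when adjusted over the list alone). FOSB was joined by KLF10 (-1.21 ± 0.26), KLF6 (-0.94 ± 0.19), the kinase SGK1 (-0.82 ± 0.14) and the phosphatase DUSP1. This list's median was -0.12 (adjusted p = 0.00200), and the call was lost with an estimated correlation (adjusted p = 0.0893). Of 35 short-lived zinc finger and signalling mRNAs, 3 fell and 0 rose (9 fell and 2 rose when adjusted over the list alone). They were TIPARP (-0.84 ± 0.12), RGS1 (-0.66 ± 0.15) and CDKN1A. Its median was -0.13 (adjusted p = 0.0148; adjusted p = 0.242 with an estimated correlation). This call was also lost without array 5 or 17.

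Of 41 NF-kB targets in Raji after Bay-11, CXCL8 and CD69 fell, 0 rose and 39 were not called (0 rose and 2 fell when adjusted over the list alone). The list's median was 0.07 (adjusted p = 0.988). NFKBIA, which encodes IkB alpha, had a change of -0.51 ± 0.19 that was not called (adjusted p = 0.176), and TNFAIP3 one of 0.27 ± 0.22 (adjusted p = 0.557). Among pathway components, the BAFF family receptor TNFRSF17 fell (-0.83 ± 0.18). Of 26 heat shock genes, HSPA1B rose (0.60 ± 0.14, adjusted p = 0.0429), and whether its probe also binds transcripts of the near-identical copy HSPA1A was not tested. The pro-apoptotic BCL2 family member BMF (1.25 ± 0.26) and the mTOR inhibitor DDIT4 (0.88 ± 0.16) rose, and PPP1R15A, a phosphatase subunit of the unfolded protein response, fell (-0.71 ± 0.12). The zinc exporter SLC30A1 fell (-0.94 ± 0.22). Other large increases were those of SNORD13 (1.67), TMEM107 (1.60), the RNA polymerase I subunit POLR1B (1.54), SNORD34 (1.42) and TAOK1 (1.33). BEGAIN (-1.38) and SNHG10 (-1.11) were among the largest decreases.

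Leaving out 1 array lowered the count of 161 genes to 37, 34 or 47 without the Raji control array numbered 16, 17 or 18, and to 29 or 27 without the Bay-11 array numbered 4 or 6. Of 26 named genes that were called, 11 held with any 1 array left out and 15 were lost at least once. Those that held were FOSB, CD69, CDKN1A, GADD45A, AEN, SGK1, TIPARP, SNORD46, SNORD34, POLR1B and BEGAIN. CXCL8 was lost without control array 17 (adjusted p = 0.0503), and PPP1R15A (adjusted p = 0.0567) and TMEM107 (adjusted p = 0.0818) without Bay-11 array 6. DDIT4 and SNHG10 were lost without array 4, 6, 16 or 18 (highest adjusted p = 0.0729 and 0.156), SNORD13 without array 4, 6, 17 or 18 (highest adjusted p = 0.0818) and TAOK1 without array 4, 6, 16 or 17 (highest adjusted p = 0.0855). FAS, KLF6, KLF10 and BMF were called with array 5 left out but lost without each of the other 5 arrays (highest adjusted p = 0.0826, 0.145, 0.214 and 0.161). HSPA1B, RGS1, SLC30A1 and TNFRSF17 were lost in all 6 omissions (highest adjusted p = 0.234, 0.208, 0.176 and 0.155). With both arrays in doubt (7 and 10) left out, which come from DG75 but share the estimate of the spread, 487 genes were called, 286 up and 201 down, the 161 among them. Up and down counts were 14 and 21 with median centring, 638 and 2 with no normalization between arrays and 1613 and 59 in the deposited processed values.

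In Raji, probe signals of several small nucleolar RNAs were lower after TPCK, and histone genes were higher as a list. SNORA33 fell 3.02-fold (-1.59 ± 0.13, adjusted p = 1.15e-05), and SNORD30 (-1.64 ± 0.32), SNORD14A (-1.55 ± 0.23) and SNORD48 (-1.42 ± 0.25) were also lower. RNU6ATAC, a small nuclear RNA of the minor spliceosome, rose 2.97-fold (1.57 ± 0.13, adjusted p = 1.15e-05), and SNORD46 rose as it did after Bay-11 (1.49 ± 0.16). SNORD54 was undetected on all TPCK arrays and at least 2.12-fold lower there. After TPCK, 47 genes changed, 25 up and 22 down, and 22 of them by over 2-fold.

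Of 20 histone genes, 2 rose in Raji after TPCK and 0 fell (6 rose when adjusted over the list alone). H3C10 was at least 2.0-fold higher and H2BC21 at least 1.57-fold higher, both undetected on control arrays. Mean raw signal per probe was 171 to 202 on those arrays and 243 to 282 on TPCK arrays. The list's median change was 0.28 (camera adjusted p = 2.51e-07, and adjusted p = 0.00481 with an estimated correlation). Of 22 p53 targets, GADD45A (-0.70 ± 0.15) and CDKN1A (-0.64 ± 0.13) fell and 0 rose (5 fell when adjusted over the list alone), with a median of -0.23 (adjusted p = 6.67e-06; adjusted p = 0.00481 with an estimated correlation). With no normalization between arrays these 2 genes turned to 0.014 (adjusted p = 0.961) and 0.062 (adjusted p = 0.824), while the median of all genes was 0.66, against 0.014 when normalized. Of 33 immediate early genes, FOSB (-1.06 ± 0.16), KLF6 (-0.96 ± 0.19) and SGK1 (-0.70 ± 0.14) fell and 0 rose (the same 3 and 0 when adjusted over the list alone). Their list had a median of -0.14 (adjusted p = 0.000126; adjusted p = 0.0250 with an estimated correlation). That call was lost with median centring (adjusted p = 0.138).

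None of the 41 NF-kB targets was called in Raji after TPCK, where limma gave 0 up and 0 down over all genes and also when adjusted over the list alone. The list's median was 0.01 (adjusted p = 0.767). CXCL8 had a change of -0.64 ± 0.19 (adjusted p = 0.266), CD69 -0.22 ± 0.18 (adjusted p = 0.999) and NFKBIA -0.39 ± 0.19 (adjusted p = 0.775). CHAC1, a glutathione-degrading enzyme of the ATF4 response, was at least 1.07-fold higher and undetected on control arrays. TMEM107 (1.54 ± 0.28) and the olfactory receptor gene OR51I1 (1.39 ± 0.18) rose, and BEGAIN fell (-1.58 ± 0.21).

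The count of 47 genes fell to 22, 19 or 26 without the Raji control array numbered 16, 17 or 18, and to 22, 19 or 26 without the TPCK array numbered 1, 2 or 3. Of 18 named genes that were called, 10 held with any 1 array left out, among them FOSB, H2BC21, H3C10, RNU6ATAC, SNORA33 and SNORD46, and 8 were lost at least once. GADD45A, SGK1 and SNORD30 were lost in all 6 omissions (highest adjusted p = 0.233, 0.141 and 0.164). CDKN1A and SNORD48 held only without array 18 (highest adjusted p = 0.237 and 0.109), KLF6 and TMEM107 only without array 1 (0.194 and 0.105) and CHAC1 only without array 2 (0.172). When arrays 7 and 10 were left out, 65 genes were called, 36 up and 29 down. Up and down counts were 11 and 28 with median centring, 5054 and 5 with no normalization between arrays and 167 and 15 in the deposited processed values.

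In DG75, 66 genes changed after Bay-11, 47 up and 19 down, and 16 of them by over 2-fold. CXCL8 fell 2.80-fold (-1.48 ± 0.19, adjusted p = 0.000908) and CD69 2.21-fold (-1.15 ± 0.18, adjusted p = 0.00747). The chemokine CCL3L3, which has near-identical copies, fell (-1.24 ± 0.23). SNORD46 rose 7.31-fold (2.87 ± 0.16, adjusted p = 3.19e-08) and RNU11, a small nuclear RNA of the minor spliceosome, rose 4.59-fold (2.20 ± 0.19, adjusted p = 1.25e-05).

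Of 41 NF-kB targets in DG75 after Bay-11, 3 fell and 0 rose (5 fell and 2 rose when adjusted over the list alone). They were CXCL8, CD69 and NFKBIZ (-0.52 ± 0.10, adjusted p = 0.0362), an inducible nuclear IkB protein. The list's median was -0.01 (adjusted p = 0.335). NFKBIA (-0.71 ± 0.19, adjusted p = 0.0939) and NFKB2 (0.99 ± 0.22, adjusted p = 0.0544) were not called. Of 33 immediate early genes, SGK1 fell (-0.95 ± 0.14) and ID3, an inhibitor of basic helix-loop-helix transcription factors, rose (0.90 ± 0.14), with 7 down and 2 up when adjusted over the list alone. None of the 22 p53 targets was called by limma, over all genes or when adjusted over the list alone (median -0.02, adjusted p = 0.928). HSPA1B was 1 of 26 heat shock genes to rise (0.65 ± 0.14, adjusted p = 0.0428). TMEM107 (2.01), RNU6ATAC (1.32) and ZSWIM3 (1.32) rose, and EPOR was at least 1.94-fold higher and undetected in controls. KBTBD8 (-0.96) fell, SYT16 was at least 1.46-fold lower, and CLOCK fell (-1.03) by a probe whose sister probe went the other way. With camera, 0 lists were called.

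The count of 66 genes depended on single arrays. It was 28, 38 or 1061 without the Bay-11 array numbered 10, 11 or 12, and 21, 15 or 38 without the control array numbered 13, 14 or 15. Of 16 named genes that were called, CXCL8, SGK1, SNORD46, RNU11, RNU6ATAC and TMEM107 held with any 1 array left out, and the other 10 were lost at least once. CD69 (adjusted p = 0.0594) and ID3 (adjusted p = 0.0520) were lost without control array 14, and SYT16 without control array 13 (adjusted p = 0.0666). KBTBD8 was lost without array 10, 13 or 14 (highest adjusted p = 0.0842), ZSWIM3 without 10, 14 or 15 (0.125) and CLOCK without 11, 14 or 15 (0.150). CCL3L3 was lost without array 11, 13, 14 or 15 (highest adjusted p = 0.119) and HSPA1B without 10, 11, 13 or 14 (0.1803). NFKBIZ and EPOR held only without array 12 (highest adjusted p = 0.151 and 0.147). The count was 35 without arrays 7 and 10, 21 up and 14 down, of which 29 were among the 66. With no normalization between arrays 10 rose and 0 fell.

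In DG75, probe signals of many small nucleolar RNAs and levels of a few NF-kB targets were lower after TPCK. SNORD14A, one of a family of near-identical copies, fell 4.23-fold (-2.08 ± 0.23, adjusted p = 0.000121), followed by SNORD30 (-1.95 ± 0.32), SCARNA9 (-1.86 ± 0.19), SNORD14D (-1.76 ± 0.29), SNORD100 (-1.69 ± 0.18) and SNORA32 (-1.66 ± 0.24). RNU6ATAC rose 5.66-fold (2.50 ± 0.13, adjusted p = 1.96e-08) and RNU11 4.36-fold (2.13 ± 0.19, adjusted p = 8.26e-06). CXCL8 fell 2.69-fold (-1.43 ± 0.19, adjusted p = 0.000637). In all, 53 genes changed, 18 up and 35 down, and 25 of them by over 2-fold.

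Of 41 NF-kB targets in DG75 after TPCK, 3 fell and 0 rose (4 fell and 3 rose when adjusted over the list alone). They were CXCL8, CD69 (-1.06 ± 0.18) and the anti-apoptotic BCL2A1 (-1.03 ± 0.21, adjusted p = 0.0359). The list's median was 0.11 (adjusted p = 0.924), and NFKBIA had a change of -0.54 ± 0.19 (adjusted p = 0.286). Of 33 immediate early genes, SGK1 (-0.75 ± 0.14) and BTG1 (-0.53 ± 0.11) fell and ID3 rose (0.75 ± 0.14), with 3 down and 1 up when adjusted over the list alone. None of the 20 histone genes was called by limma over all genes (2 rose when adjusted over the list alone), but the list was higher (median 0.16, adjusted p = 0.0398). That call was lost with an estimated correlation (adjusted p = 0.238), and without array 7 (adjusted p = 0.436), array 8 (adjusted p = 0.209) or the control array numbered 13 (adjusted p = 0.0968) or 15 (adjusted p = 0.0608). None of the 22 p53 targets was called by limma (median -0.05, adjusted p = 0.924). HSPA1B (0.68 ± 0.14) rose. SNORD46 (1.88), the shelterin component TINF2 (1.28), SNORA64 (1.06) and PLEKHF1 (1.05) also rose. The 3 measured fibroblast and epithelium markers had a median of 1.38 in this comparison, which includes array 7.

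The count of 53 genes fell to 30 or 28 without the control array numbered 13 or 14 and to 33 without the TPCK array numbered 9. Of 19 named genes that were called, 12 held with any 1 array left out, among them CXCL8, RNU6ATAC, RNU11, TINF2 and SNORD14A, and 7 were lost at least once. BCL2A1 and HSPA1B were lost without array 7, 9, 13 or 14 (highest adjusted p = 0.216 and 0.203), SGK1 without 8, 9, 13 or 14 (0.0825) and CD69 without 9 or 14 (0.0717). ID3 held only without array 15 (highest adjusted p = 0.142), and BTG1 and SNORA64 were lost in all 6 omissions (0.173 and 0.127). Without arrays 7 and 10, 65 genes were called, 25 up and 40 down, of which 41 were among the 53. Up and down counts were 12 and 1 with no normalization between arrays. They were 39 and 4 in the second deposited table, whose columns for these groups hold raw signals.

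**Figure D1:**
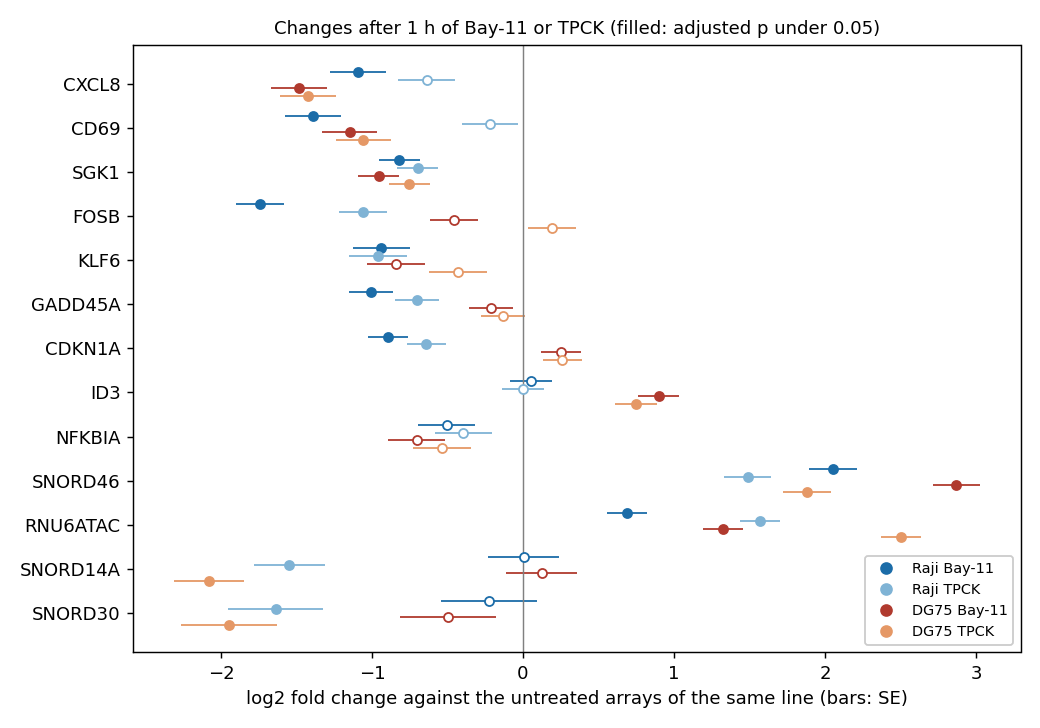
Log2 fold change of 13 genes in each line and treatment against the untreated arrays of that line (n = 3 arrays per group). Points are fitted changes with bars of 1 SE, and filled points have an adjusted p below 0.05; CXCL8 fell in both lines after Bay-11 and in DG75 after TPCK, and SNORD46 rose in all 4 comparisons.

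The small nuclear and nucleolar RNAs, counted here together with RN7SL1 of the signal recognition particle and RPPH1 of RNase P, were grouped after their values had been seen. Whether their probes report the mature RNAs or longer transcripts that contain them was not tested. How far the RNeasy clean-up and MessageAmp labelling retain and label RNAs this short was not tested either. Of 52 such RNAs measured, 8 rose and 0 fell after Bay-11 in Raji, and likewise 8 and 0 in DG75. After TPCK 5 rose and 11 fell in Raji, and 6 rose and 14 fell in DG75. They made up 34.0% of the genes called in Raji after TPCK and 37.7% of those called in DG75, against 0.486% of the genes tested. After Bay-11 their shares of the called genes were 4.97% in Raji and 12.1% in DG75. Across these 52 RNAs, which are not independent replicates, the TPCK changes in the lines correlated with r = 0.896 and rho = 0.901, and the Bay-11 changes with r = 0.789 and rho = 0.787. Without arrays 7 and 10 the counts up and down after TPCK were 5 and 14 in Raji and 7 and 15 in DG75, and after Bay-11 11 and 3 in Raji and 8 and 0 in DG75. The 3 that fell in Raji there were SCARNA9 (-0.58, adjusted p = 0.0291), SNORD48 (-0.56, adjusted p = 0.0400) and RPPH1 (-0.50, adjusted p = 0.0450).

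**Figure D2:**
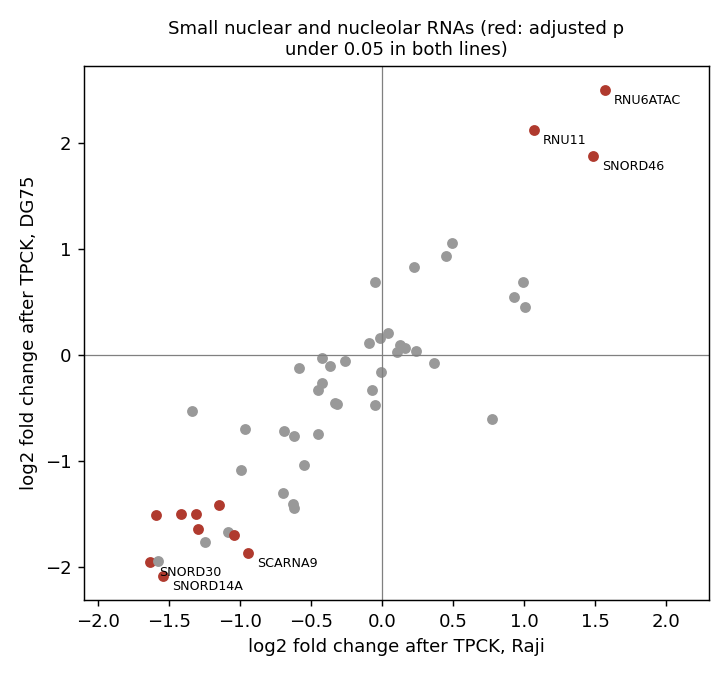
Log2 fold change after TPCK in DG75 against that in Raji for each of the 52 small RNAs (n = 3 arrays per group). Red points have an adjusted p below 0.05 in both lines; RNU6ATAC lies at 1.57 in Raji and 2.50 in DG75, and SNORD14A at -1.55 and -2.08.

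TPCK and Bay-11 were compared directly within each line, at doses that differed (75 and 50 µM). In both lines TPCK arrays gave lower probe signals for several small nucleolar RNAs. SNORD38A was lower by a log2 difference of -1.90 (95% interval -2.17 to -1.64, adjusted p = 6.11e-07) in Raji and -1.89 (-2.16 to -1.63, adjusted p = 6.63e-07) in DG75. SNORD14A differed by -1.55 in Raji and -2.20 in DG75, and EBLN2 by -1.96 and -1.57. In Raji, CD69 was higher after TPCK than after Bay-11 (1.17, 95% interval 0.79 to 1.56, adjusted p = 0.00782), as were H3C10 (close to background after Bay-11, where 1 of 3 arrays detected it), NHLRC2 (1.05), ZNF101 (1.04), OR51I1 (1.01) and AGO3 (1.00). SNORD14D (-1.64), SNORA32 (-1.35) and SNORD54 (at least 2.09-fold, undetected after TPCK) were lower in Raji. In DG75, SNORD14C (-2.01), SNORD100 (-1.76) and SNORD36C (-1.65) were lower, and SNAR-A1 (1.24), RNU6ATAC (1.18 ± 0.13) and LRP5L (0.70) were higher after TPCK. NFKBIA differed by 0.11 in Raji (95% interval -0.29 to 0.51, adjusted p = 0.844) and 0.17 in DG75 (-0.23 to 0.57, adjusted p = 0.732), and neither was called.

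In Raji, 29 genes differed between TPCK and Bay-11, 13 higher and 16 lower after TPCK. Of 20 histone genes, H3C10 was called up after TPCK and 0 down (7 up when adjusted over the list alone). As a list they were higher, with a median of 0.28 (adjusted p = 0.000516), a call lost with an estimated correlation (adjusted p = 0.0625). In DG75, 20 genes differed, 3 higher and 17 lower, 17 of them small nuclear or nucleolar RNAs. There, histone genes (median 0.18), NF-kB targets (0.05) and ribosomal proteins (0.05) were higher as lists, each with an adjusted p = 0.0127 and 0 members called over all genes by limma. With an estimated correlation these became adjusted p = 0.125 for histone genes and adjusted p = 0.0610 for both other lists, and without arrays 7 and 10 adjusted p = 0.264 for histone genes, adjusted p = 0.264 for NF-kB targets and adjusted p = 0.673 for ribosomal proteins. Of 12 named genes that were called in Raji, EBLN2, SNORD38A and SNORD54 held with any 1 array left out and 9 were lost at least once. CD69, H3C10 and SNORD14A were lost without array 1 or 6 (highest adjusted p = 0.0589, 0.0578 and 0.0578), ZNF101 without 1, 4 or 6 (0.0734), SNORA32 without 1, 2, 5 or 6 (0.187) and OR51I1 without 3, 4, 5 or 6 (0.115). NHLRC2 held only without array 2 (highest adjusted p = 0.255), and AGO3 and SNORD14D were lost in all 6 omissions (0.289 and 0.126). Of 9 named genes called in DG75, 6 held, while EBLN2 was lost without array 7, 8 or 10 (highest adjusted p = 0.133), LRP5L without 7, 8, 10 or 11 (0.113) and SNAR-A1 without 8, 9, 10 or 11 (0.189). The Raji count was 7 or 18 without the TPCK array numbered 1 or 2, 13 or 7 without the Bay-11 array numbered 4 or 6, and 65 (28 up and 37 down) without arrays 7 and 10. The DG75 count was 12 without array 7 and 18 without both arrays. Its NF-kB call was lost without array 7 (adjusted p = 0.222), 11 (adjusted p = 0.0804) or 12 (adjusted p = 0.0993), its histone call without array 7 (adjusted p = 0.171) or 11 (adjusted p = 0.112), and its ribosomal protein call without array 10 (adjusted p = 0.138). Up and down counts in Raji were 5 and 15 with median centring, 1 and 2 with no normalization between arrays and 32 and 195 in the deposited processed values. With the replicate number as a block these last became 38 and 151, and OR51I1 was lost (adjusted p = 0.0614, against 0.0266 without the block). With no normalization between arrays, DG75 gave 0 and 5.

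The untreated lines differed far more than the treatments did. Genes linked to Epstein-Barr virus latency were much lower in DG75, the line without the virus. Virus status cannot be told apart here from any other difference between the lines. EBI3, a cytokine subunit induced by the virus, was at least 111-fold lower, the low affinity IgE receptor FCER2 at least 27.7-fold and the chemokine CCL22 at least 24.6-fold, all undetected in DG75 controls. The protease CTSH was at least 118-fold lower. The anti-apoptotic genes BCL2L1 (-3.47 ± 0.17, adjusted p = 7.92e-11) and BCL2 (-1.78 ± 0.16) were also lower in DG75. The chemokine CXCL8 was higher in DG75 (2.35 ± 0.19, adjusted p = 2.28e-08). In all, 4163 genes differed, 2214 higher and 1949 lower in DG75.

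Of 27 host genes associated with virus latency, 21 were lower and 3 higher in DG75 (22 and 3 when adjusted over the list alone), with a median of -2.52 (adjusted p = 8.41e-15; adjusted p = 0.000649 with an estimated correlation). Of 41 NF-kB targets, 24 were lower and 3 higher (26 and 4 when adjusted over the list alone), with a median of -0.83 (adjusted p = 4.91e-09; adjusted p = 0.000518 with an estimated correlation). The 3 higher were ITGAL (0.88), ITGB2 (0.41) and TNFAIP2 (undetected in Raji controls and close to background in DG75) among the latency genes, and CXCL8, TNFAIP2 and NFKBIZ (0.33) among the NF-kB targets. The lists share many members, among them EBI3, CCL22, CCR7, CFLAR, BCL2A1 and TNFAIP2, so their calls are not independent. The chemokine CCL3 (-5.59 ± 0.17) and the chemokine receptor CCR7 (-4.63 ± 0.15) were lower. Of 31 pathway components, 6 were lower and 7 higher, such as PRKCB (at least 33-fold lower) and TNFRSF17 (1.47 ± 0.18). Of 19 BCL2 family genes, 8 were lower and 5 higher, namely BNIP3 (2.96 ± 0.16), BMF (2.21 ± 0.26), BIK (1.07), PMAIP1 (1.03) and BNIP3L (0.89). The caspase-8 regulator CFLAR (-2.53 ± 0.25) and the inflammatory caspase CASP1 (-2.06 ± 0.19) were lower. Of 26 heat shock genes, 5 were higher and 5 lower. The higher were HSPA1A (2.66 ± 0.19), HSPB1 (2.42 ± 0.18), HSPA4L (undetected in Raji controls), HSPA1L (0.65) and BAG3 (0.53), and the lower HSPA6 (at least 2.91-fold), HSPH1 (-1.16), FKBP4 (-0.88), HSPA1B (-0.82) and HSPA8 (-0.39). Further genes far lower in DG75 were ACKR3, PLAC8, PTGER4 and SLAMF1, at least 57.2-fold, 42.3-fold, 37.5-fold and 35.3-fold. LRRN3 and ADM were at least 6.78-fold and 7.48-fold higher, and RAB40B (3.42), LXN (3.32), AKAP19 (3.25) and LEF1 (3.21) were also higher. The count was 3520 to 3760 with 1 array left out and 4815 without arrays 7 and 10. With no normalization between arrays 1910 were higher and 688 lower.

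The response of the lines was compared directly. Differences are the signed change in DG75 minus that in Raji, so a higher value can mean a smaller fall in DG75. No gene was called as responding differently in DG75 and Raji to Bay-11 or to TPCK, where limma gave 0 genes for each, against 692 and 595 genes with an unadjusted p under 0.05. Without arrays 7 and 10, 3 genes were called for Bay-11 and 0 for TPCK. The signed Bay-11 change was higher in DG75 for FOSB (log2 difference 1.40, adjusted p = 0.0116). It was lower for CCL3L3 (-1.37, adjusted p = 0.00349) and MIR181A2HG (-1.65, adjusted p = 0.0116). With all arrays, FOSB fell less in DG75 (-0.46, not called) than in Raji (-1.74). The 22 p53 targets differed as a list, with a Bay-11 effect higher in DG75 by a median of 0.27 (adjusted p = 1.69e-05; adjusted p = 0.0104 with an estimated correlation). Over all genes 0 members were called by limma, and 6 were higher when adjusted over the list alone. The short-lived zinc finger and signalling mRNAs differed in the same direction (median 0.19, adjusted p = 0.0473; adjusted p = 0.494 with an estimated correlation). The TPCK effect was higher in DG75 for immediate early genes (median 0.20, adjusted p = 0.0285; adjusted p = 0.257 with an estimated correlation) and for p53 targets (median 0.13, adjusted p = 0.0285; adjusted p = 0.257 with an estimated correlation). For the same inhibitor, each of these lists was called lower in Raji and was not called in DG75. The p53 call for Bay-11 held with any 1 array left out. The short-lived list was lost without array 4, 5, 10, 11, 12, 13, 14, 17 or 18 (adjusted p = 0.0511 to 0.249). For TPCK, the immediate early list was lost without array 2, 3, 7, 14, 15, 16 or 18 (adjusted p = 0.0524 to 0.247) and the p53 list without array 2, 3, 7, 8, 13, 15, 16 or 18 (adjusted p = 0.0638 to 0.151).

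Across all genes, which are not independent replicates, Bay-11 changes in the lines correlated with r = 0.466 and rho = 0.460, and TPCK changes with r = 0.265 and rho = 0.211. After Bay-11 13 genes rose in both lines, where 0.413 would be shared by independent lists, and 9 fell, where 0.119 would. CD69, CXCL8, SGK1, TIPARP and KBTBD8 were among those that fell. After TPCK 6 genes rose in both lines (0.0421 for independent lists) and 10 fell (0.0720). SGK1 was the only one of the 10 that is not a small nuclear or nucleolar RNA. Within Raji 9 genes rose after both inhibitors (0.220) and 9 fell (0.138), among them FOSB, KLF6, CDKN1A, GADD45A and SGK1. Within DG75 8 rose after both (0.0791) and 9 fell (0.0622), among them CXCL8, CD69 and SGK1. The inhibitors' changes correlated with r = 0.514 in Raji and 0.533 in DG75, against 0.500 in 50 simulations of unchanged groups that share controls. Simulations shared 0 calls, but no gene was changed in them. That count therefore cannot tell how far shared controls add to the overlap of called genes. Covariance was 0.0357 in Raji and 0.0497 in DG75, against 0.0220 simulated. The same simulated value served both lines, so the excess was not measured against each line's own spread. With 3 controls per line no split leaves 2 controls to each inhibitor, so part of the excess may come from shared controls.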

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

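The split counts were planned before the results were seen, and the tests on array 7 were chosen after.

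The lines differed in 4 list results, given as the signed change in DG75 minus that in Raji. For the same inhibitor, each of these lists was called lower in Raji and was not called in DG75. The Bay-11 effect on p53 targets was higher in DG75 than in Raji (median 0.27, adjusted p = 1.69e-05; adjusted p = 0.0104 with an estimated correlation). So was that on short-lived zinc finger and signalling mRNAs (median 0.19, adjusted p = 0.0473), a call lost with an estimated correlation (adjusted p = 0.494). The TPCK effect was higher in DG75 for immediate early genes (median 0.20, adjusted p = 0.0285) and p53 targets (median 0.13, adjusted p = 0.0285), and both calls were lost with an estimated correlation (adjusted p = 0.257 for each). Without arrays 7 and 10, 1 list was called for Bay-11, the p53 targets (adjusted p = 6.71e-06). For TPCK 2 were called, the p53 targets and the histone genes (adjusted p = 0.0458 for both). The histone genes rose less in DG75 (median difference -0.23). The real split and others drawn at random within the lines made 100. Of these, 10 gave at least the real 2 lists for Bay-11 (highest other 3), the real one included. For TPCK 14 gave at least the real 2 (highest other 4), the real one included. Such splits leave treatment effects in the arrays, so they cannot decide whether chance gave these counts, and chance is not excluded. For genes, a real count of 0 is reached by any split, 100 of 100 for Bay-11 (highest other 978) and for TPCK (highest other 7), so these counts say nothing about chance. The split with 978 genes exchanged treated and untreated labels in DG75 alone, which turns the difference of the effects into their sum, and no other structure of the samples was tested.

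The DG75 TPCK array numbered 7 carried 50 probes above log2 8 that were detected on that array alone and were left out of the gene tests. Of 15 listed fibroblast and epithelium markers, 13 had a probe and 12 were detected on it, against at most 1 on any other DG75 array. The brightest were COL1A2 at 10.03, COL1A1 at 9.83, DCN at 9.83, COL3A1 at 9.29 and KRT19 at 9.15. Against Raji RNA in this array, 9 of the 12 markers were detected on none of the 9 Raji arrays, and against TPCK treatment, 9 were detected on none of the other 5 TPCK arrays. RNA of another human cell type mixed into this array may account for the 12 markers, and its source, and a wrong label or sample for part of it, stay open.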

How the results depend on the processing

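The exclusion of arrays 7 and 10 was chosen after the data had been seen, and all other alternatives were planned. The chip was not named, so a chip block was not run, and the second deposited table shares a scale only within Raji, where it holds processed values, and for DG75 TPCK against control, where it holds raw signals. Array numbers part all control arrays from all treated ones, so a block by number could not be separated from treatment. The cause of a shift was not tested unless stated. Dim probes near background limit what can be seen, as do 3 arrays per group.

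Gene counts are given in the order Raji Bay-11 (161), Raji TPCK (47), DG75 Bay-11 (66), DG75 TPCK (53), Raji TPCK against Bay-11 (29), DG75 TPCK against Bay-11 (20), the untreated lines (4163) and the Bay-11 and TPCK differences between lines (0 each, with 692 and 595 at an unadjusted p under 0.05 by limma), and only shifts beyond 1.5 times are listed. With no normalization between arrays they were 640, 5059, 10, 13, 3, 5 and 2598, and the median of all genes was 0.39, 0.66, 0.35, 0.39, 0.22, 0.017 and 0.25, against 0.0056, 0.014, 0.051, 0.017, 0.0094, -0.051 and 0.034 when normalized. CDKN1A and GADD45A turned to 0.062 (adjusted p = 0.824) and 0.014 (adjusted p = 0.961) in Raji after TPCK there. Median centring gave 35 in Raji and 30 in DG75 after Bay-11, and 1 for the Bay-11 difference. No background correction gave 46 for Raji TPCK against Bay-11 and 2 for the Bay-11 difference. Detection on all arrays tested fewer genes and gave 31 for Raji TPCK and 3 for the Bay-11 difference. All kept probes gave 66 for Raji TPCK against Bay-11 and 4 and 1 for the differences. The compared groups alone gave 413 and 4 after Bay-11 in Raji and DG75, 26 for DG75 TPCK and 0 for DG75 TPCK against Bay-11 with limma. Array weights gave 1132, 139 and 157 for the first 3 counts, 686 for Raji TPCK against Bay-11 and 4 and 4 for the differences. Leaving out arrays 7 and 10 gave 487 in Raji and 35 in DG75 after Bay-11, 65 for Raji TPCK against Bay-11 and 3 for the Bay-11 difference.

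The deposited processed values gave 1672 for Raji Bay-11, 182 for Raji TPCK and 227 for Raji TPCK against Bay-11. With the replicate number as a block they gave 1696, 179 and 189. Deviations of same-numbered arrays correlated from -0.165 to 0.0702 in Raji pairs with a control, 0 of them over 0.1. In 3 DG75 pairs they correlated from 0.0479 to 0.104, 1 of them over 0.1. The numbers were therefore not taken to pair those samples, though low correlations cannot exclude a pairing. For Raji TPCK against Bay-11 the numbers were taken to pair the samples. There the block ended the call of OR51I1 (adjusted p = 0.0266 before and 0.0614 after) and of BCL2L1 (0.0417 and 0.0614). It added that of RELB (0.0515 and 0.0465) and changed no other call of a named gene or list there.

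With 1 array left out, counts ran from 27 to 202, 19 to 26, 15 to 1061, 28 to 39, 7 to 24, 12 to 30 and 3520 to 3760, and from 0 to 1 and 0 to 0 for the differences. Lists called ran in the same order from 2 to 3, 3 to 3, 0 to 1, 0 to 1, 1 to 2, 1 to 5, 2 to 2, 1 to 2 and 0 to 2, and from 12 to 18 in all. The adjusted p of NF-kB targets ran from 0.856 to 0.984, 0.688 to 0.991, 0.182 to 0.564 and 0.596 to 0.998 in the 4 treatment comparisons. Correlations ran from 0.395 to 0.498 between lines for Bay-11, 0.177 to 0.295 for TPCK, and 0.396 to 0.569 and 0.359 to 0.607 between inhibitors in Raji and DG75.

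The total of 17 list calls fell to 7 with an estimated correlation, with 1 for Raji Bay-11, 0 for DG75 TPCK, 0 for TPCK against Bay-11 in either line, and 1 and 0 for the differences. For DG75 TPCK (main 1) the count was 0 with no background correction, no normalization between arrays, detection on all arrays, the second deposited table (raw signals) with or without the block, or without arrays 7 and 10, and 2 with median centring or no detection filter. For DG75 Bay-11 (main 0) it was 1 with no normalization between arrays or median centring. For Raji TPCK (main 3) it was 5 in the deposited processed values with or without the block. For Raji TPCK against Bay-11 (main 1) it was 2 with no normalization between arrays or median centring and 0 with detection on all arrays or the deposited processed values with or without the block. For DG75 TPCK against Bay-11 (main 3) it was 1 with detection on all arrays and 0 without arrays 7 and 10. For the Bay-11 difference (main 2) it was 1 with no normalization between arrays, median centring, no detection filter, the compared groups alone, array weights or without arrays 7 and 10, and for the TPCK difference (main 2) it was 0 with no normalization between arrays or median centring.

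The correlation between lines was 0.502 for Bay-11 and 0.304 for TPCK with no background correction, 0.328 for TPCK in the second deposited table, which sets processed Raji against raw DG75 values, and 0.687 and 0.782 over genes called in either line. Between inhibitors in DG75 it was 0.645 without arrays 7 and 10. Values of named genes with 1 array left out kept their side of the threshold in 1328 cases, and in 8 more where the value of an uncalled gene moved, lost it in 212 and gained it in 6, which fewer samples can bring about.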

Other observations

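The tests on array 10 and on the small RNAs were chosen after the results were seen, and the split counts before.

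Single members of stress and B cell lists also differed between the untreated lines, and the lists given here were not called. Of 28 genes of the ATF4 and unfolded protein response, 12 were higher in DG75 and 6 lower (13 and 9 when adjusted over the list alone), with a median of 0.31 (adjusted p = 0.386). The cysteine synthesis enzyme CTH (1.85 ± 0.14), the pseudokinase TRIB3 (1.17 ± 0.18) and VLDLR (at least 2.0-fold) were higher. Of 23 NRF2 genes, 7 were lower and 4 higher (7 and 4 when adjusted over the list alone; adjusted p = 0.743), with the quinone reductase NQO1 at -2.76 ± 0.25 and the 4 higher being the glutathione reductase GSR (1.40 ± 0.15), GCLC (0.68), HMOX1 and ABCC2, the last 2 undetected in Raji controls and close to background in DG75. The metallothioneins MT2A (-1.88 ± 0.22) and MT1X (-1.13 ± 0.16) were lower. Of 33 immediate early genes, 9 were lower and 4 higher (12 and 6 when adjusted over the list alone; adjusted p = 0.503), with DUSP5 at -2.27 ± 0.19 and the 4 higher being the helix-loop-helix inhibitor ID1 (3.19 ± 0.28), ID3 (1.75), IER3 (1.02) and MYC (0.80). Of 35 B cell identity genes, 10 were lower and 8 higher (10 and 8 when adjusted over the list alone; adjusted p = 0.795). The fetal globin gene HBG2, singled out after its values had been seen, was detected on all 3 Raji control arrays (mean 8.73) and on 0 DG75 control arrays.

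Small RNAs, as grouped above, changed after TPCK in both lines, with 11 called lower and 5 higher in Raji and 14 lower and 6 higher in DG75, of 52 measured. Against a change of the host transcripts, the 18 of 25 lower calls whose containing gene was measured had a median of -1.47 for the small RNA and -0.035 for the host (range -0.33 to 0.33), and 0 of 9 hosts were called by limma. Against a uniform loss of small RNAs in the RNA clean-up, 6 were called higher in DG75, and against array differences within 1 line, the changes in the lines correlated with r = 0.896. Host levels after 1 h do not measure host transcription, so they cannot decide whether transcription of the hosts fell. A change of the host for the other 7 lower calls, which had no single measured containing gene, stays open. So do a loss in clean-up that differs between small RNAs and a batch shared by TPCK arrays or by control arrays of both lines. Each of these may account for part of the change. An effect of TPCK itself on these RNAs stays open as well and was not tested.

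On the DG75 Bay-11 array numbered 10, 205 probes of 186 genes that were bright on the DG75 control arrays were over 2 log2 units below their mean there. For the 128 probes with another bright probe of the same gene, the median change was -3.41 for the probe and -0.16 for the other probe (quartiles -1.93 and 0.21). Against Bay-11 treatment, the same probes had a median change of -0.19 on the other DG75 Bay-11 arrays, and against a low signal of the array, its mean raw signal per probe was 272. Failure of single probes on this array is a candidate explanation, and for the 29.7% of probes whose partner was also lower by over 1 log2 unit a loss of the transcript stays open.

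The splits of the arrays of each comparison number 10, the real one included, too few for a share under 0.05. Splits with at least the real gene count, the real one included, were 1 for Raji Bay-11 (real 161, highest other 0), 1 for Raji TPCK (47 and 0), 1 for DG75 Bay-11 (66 and 1), 1 for DG75 TPCK (53 and 0), 1 for Raji TPCK against Bay-11 (29 and 0), 2 for DG75 TPCK against Bay-11 (20 and 762) and 1 for the untreated lines (4163 and 0). The Raji arrays used here carry no replicate number, so splits that part as many pairs could not be picked out. For lists called the counts were 1 for Raji Bay-11 (3 and 1), 1 for Raji TPCK (3 and 1), 10 for DG75 Bay-11 (0 and 1, where any split reaches 0), 2 for DG75 TPCK (1 and 2), 3 for Raji TPCK against Bay-11 (1 and 1), 1 for DG75 TPCK against Bay-11 (3 and 0) and 10 for the untreated lines (2 and 2). The split with 762 genes set the arrays numbered 9, 10 and 11 against those numbered 7, 8 and 12. It puts the arrays in doubt, 7 and 10, on opposite sides. It may reflect a structure of these samples other than their treatment, which was not tested.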
